A study of Rattus norvegicus and Mus musculus with 9 samples.

How the data were processed

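Total RNA was taken from rat ES cells, rat embryonic fibroblasts and mouse ES cells, and biotin-labelled single-stranded DNA made from it was hybridized to arrays with 1 sample per array, per the labels' protocols. The authors deposited log2 values per probe set in 2 tables, for 6 rat arrays and 3 mouse arrays on another platform. That the values are on the log2 scale was read from their range, since the background correction, normalization and summary of probes are not given in the sources used here. The 2 tables were normalized separately, so differences in level were tested only within the rat table. Array medians within each table differed by less than 0.1, and the deposited values were used without further normalization. A genome build was not given in the sources used here, and no coordinates are printed.

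Genes were named through the platform annotation supplied with the tables, which can be old. Of 29215 rat probe sets, 15310 had 1 gene symbol, 323 had several and 13582 had none listed. Of 35557 mouse probe sets, 21789 had 1 symbol, 1621 had several and 12147 had none listed. Gene IDs of 15279 named rat probe sets were found in the RefSeq gene table of assembly GRCr8, and 0 of these had another symbol there. That table was used only for names and for the order of neighbouring genes. Probe sets with several symbols or none were left out. For a symbol with several probe sets, 527 in the rat table, the probe set with the highest mean over all arrays of the table was kept, which left 14506 rat genes and 19938 mouse genes.

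Rat ES cells and rat fibroblasts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group only), with Benjamini-Hochberg adjustment over all genes tested. A gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size. There was no filter on level. The 32 gene lists, the rule for naming genes, the tests and most of the other settings were fixed before the data were examined. Lists were tested with camera at its preset correlation of 0.01, adjusted over the 32 lists, with camera at an estimated correlation and fry beside it. The named genes are the 8 largest and 8 smallest log2 differences among called genes whose groups do not overlap, the 3 called members with the largest difference in each list, up to 2 called members against a list's majority, and every measured member of both pluripotency lists. Between mouse ES and rat ES cells they are the 6 largest and 6 smallest differences of mean percentile among list members whose groups do not overlap. Lists of lineage, endothelial, blood, muscle, cartilage, adipocyte, keratinocyte and germ cell markers stand for other cell types that a culture could hold.

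On simulated data for the rat comparison, with 14506 genes of which 200 were changed, limma called 100% of those changed 2.83-fold and 100% of those changed 8-fold, with 0 unchanged genes called. The replicate numbers of the labels were checked for pairing across the rat groups. Deviations from the group means of arrays with the same number correlated at -0.00044, 0.031 and -0.0003, so the numbers were not treated as pairs.

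Mouse and rat values were compared only as ranks. Spearman's rho was computed across 12114 symbols shared by both tables, case ignored, for each pair of a mouse and a rat array, and the mean difference was tested by an exact permutation of the 6 rat arrays over 20 assignments. Percentiles were taken among the shared symbols within each array. The replicates were compared for identical values only after the mouse comparisons had first been computed. Any pair of rat replicates shared at most 30 identical values of 29215, while the pairs of mouse arrays shared 16691 to 20845 of 35557, and 15447 probe sets had the same value on all 3 mouse arrays. The mouse arrays correlated at r = 0.991 to 0.994, and the probe sets that were not identical differed by medians of 0.125 to 0.190 on the log2 scale, against 0.114 to 0.131 between rat replicates. The mouse arrays were kept as 3 arrays, no SD over them is printed, and 2 alternatives, chosen after seeing the data, used only genes with 3 different mouse values or averaged the mouse arrays as 1 sample.

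The alternatives for the rat comparison were quantile normalization, median centring, filters at the 25th percentile and the median of mean level, the mean of all probe sets of a gene, every probe set apart, eBayes with trend and robust settings, 3 other thresholds, the replicate number as a block and leaving out each array. For the mouse comparison they were Pearson's r, a filter at the 25th percentile of level in both tables, the mean of all probe sets, stricter gene lists, percentiles among all named genes and leaving out each array. A setting meant for linear values was not run, since the values are logarithms.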

Results

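Gene expression was measured on microarrays in rat embryonic stem (ES) cells, rat embryonic fibroblasts and mouse ES cells, with 3 arrays per group. ES cells are cultured derivatives of the early embryo that keep the capacity to form all tissues of the body, and fibroblasts are the matrix-producing connective tissue cells. Both rat groups came from the DA strain. The rat ES cells were grown in a medium the labels call 3I, a name used for media that combine inhibitors of FGF receptor, MEK and GSK3 signalling. The rat fibroblasts were grown in GMEM with 10% fetal bovine serum, and the mouse ES cells, of strain C57/BL6, in the same serum medium with leukaemia inhibitory factor (LIF). The labels say that feeder cells were removed from the mouse cultures before RNA was taken and make no such statement for the rat ES cultures. The rat arrays had median signals between 5.71 and 5.74 on the log2 scale, and the mouse arrays no higher than 4.77. The number of arrays limits the precision of every value given here.

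The first comparison asked how the transcriptome of rat ES cells differed from that of rat embryonic fibroblasts. In rat ES cells, 11 of 15 naive pluripotency factors, 11 of 13 general pluripotency factors and 19 of 31 cell cycle and DNA replication genes were called higher, and 20 of 26 fibroblast and mesenchymal identity genes were called lower. These were the 4 lists that camera called both with its preset correlation and at adjusted p = 0.0417 with an estimated correlation. Of 14506 genes tested, limma called 2996 changed at least 2-fold at a Benjamini-Hochberg adjusted p under 0.05, 1538 of them higher in rat ES cells and 1458 lower. Among these, 50 genes were at least 16-fold higher in rat ES cells and 131 were at least 16-fold lower. With no fold threshold, 8172 genes passed the same adjusted p, 4478 higher and 3694 lower. The signals of the 2 groups did not overlap in 61.5% of genes, where chance gives 10%. Within a rat group, the arrays correlated at r = 0.994 to 0.995 across probe sets, and between the groups at 0.910 to 0.915. The first principal component, which separated the 2 groups, held 95.9% of the variance. The labels do not say that the arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Medium differed between the 2 rat groups along with cell type, so no gene or list difference between them can be assigned to either one.

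The 8 largest increases in rat ES cells were in Bex4, Pou5f1, Nanog, Akr7a3, Tcl1a, Ifitm1, Dppa3 and Dnmt3l. Pou5f1, which encodes the core pluripotency transcription factor Oct4, had a signal of 11.20 ± 0.073 (log2, SD, n = 3) in rat ES cells and 4.15 ± 0.549 in fibroblasts, a 132-fold difference (log2 difference 7.04, SE 0.23, limma adjusted p = 4.97e-08). Bex4 was 134-fold higher and Nanog 106-fold higher, and Dnmt3l, a cofactor of the de novo DNA methyltransferases, was 78.3-fold higher. The fibroblast signals of these genes (3.23 ± 0.670 for Bex4, 4.40 ± 0.342 for Nanog) lay below the array medians and were not separated from background here, so their folds and their order are uncertain. The 8 largest decreases were in Thbs1, Tgfb3, Il1rl1, Enpp1, Tagln, Fbln5, Grem1 and Lox. Thbs1, the matrix glycoprotein thrombospondin, was at 6.36 ± 0.174 in rat ES cells and at 13.43 ± 0.027 in fibroblasts (log2 difference -7.07, SE 0.09, limma adjusted p = 1.72e-09). Tgfb3 fell by 6.87 on the log2 scale, the BMP antagonist Grem1 by 6.38 and the collagen cross-linking enzyme Lox by 6.32. The rat ES signals of Tgfb3 (5.02), Il1rl1 (4.81), Grem1 (4.90), Enpp1 (5.44) and Lox (5.54) also lay below the array medians. The sizes and order of these decreases are therefore uncertain too. The same limit holds for every gene named below whose signal in either rat group lay below the array medians, also where it is not repeated.

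Genes were then read by 32 lists fixed before the data were examined. In the list of naive pluripotency factors, 11 of 15 measured members were called higher in rat ES cells and none lower, with a median log2 difference of 4.58 (camera adjusted p = 5.6e-07). Besides Nanog, Tcl1a and Dppa3, the increases were in Tdh (5.51), Tfcp2l1 (5.48), Klf5 (4.73), Tbx3 (4.66), Pecam1 (4.58), Esrrb (3.86), Klf2 (2.76) and Klf4 (1.89). The other 4 members were not called: Fbxo15 differed by 0.63 and Zfp57 by 0.50, Nr5a2 by -0.10 and Nr0b1 by -0.30, the last with a limma adjusted p of 0.0529. Signals of Nr5a2 (4.09 in rat ES cells, 4.19 in fibroblasts) and Nr0b1 (4.61 and 4.92) lay below the array medians in both groups. Low expression and a probe set that does not respond cannot be told apart there. In the list of general pluripotency factors, 11 of 13 measured members were called higher and none lower, with a median of 3.33 (camera adjusted p = 1.19e-07). Gdf3 differed by 5.45, Sox2 by 4.44, Zscan10 by 4.42, Lefty1 by 4.02, the RNA-binding protein gene Lin28a by 3.33, Trim71 by 2.62, Nodal by 2.38 and the telomerase gene Tert by 2.28. Fgf4 lay near the threshold at 1.10 and fell to 0.98, under 2-fold, after quantile normalization. Phc1 (0.50) and Foxd3 (0.33) were not called. Both lists stayed called by camera at adjusted p = 0.0417 with an estimated correlation. Of 9 primed and early post-implantation markers, 3 were called higher (Zic2 4.82, Cldn6 3.80, Dnmt3b 2.55) and 1 lower (Sox4 -1.92), and the list was not called (camera adjusted p = 0.293).

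**Figure D1:**
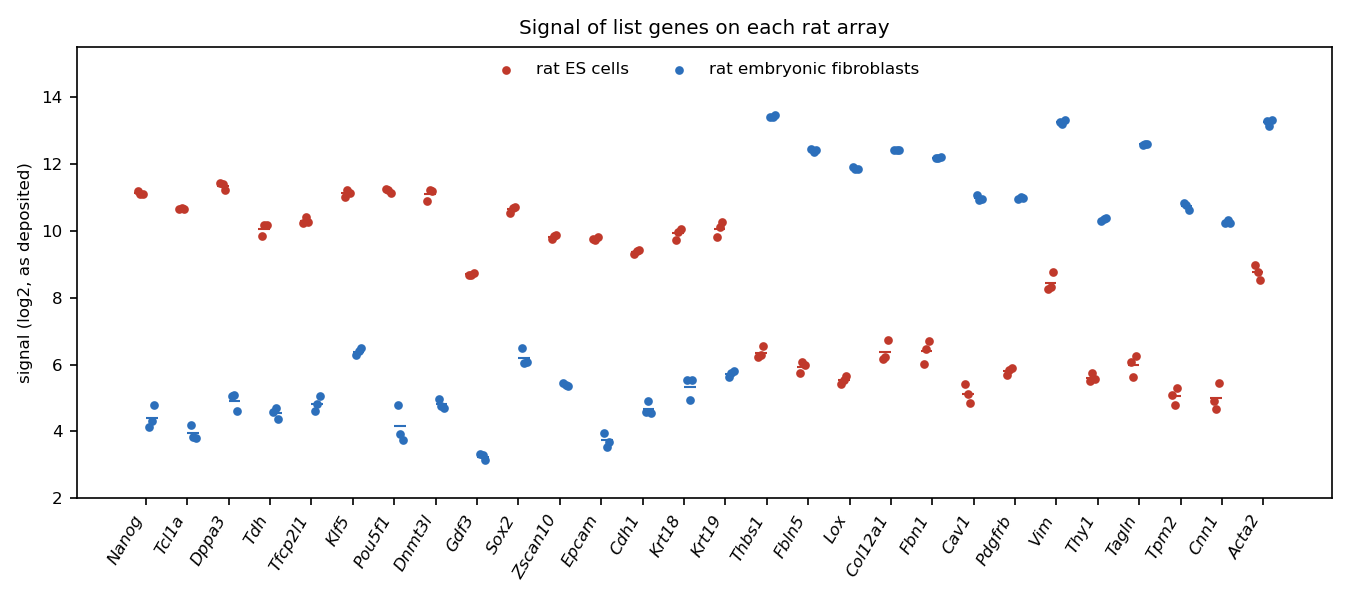
Signal of 28 list genes (log2, as deposited, vertical axis) on each of the 3 rat ES arrays (red) and 3 rat fibroblast arrays (blue), with short lines at the group means. Pou5f1 sits at 11.20 in rat ES cells and 4.15 in fibroblasts, and Thbs1 at 6.36 and 13.43.

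Of 28 fibrillar collagen and matrix genes, 23 were called lower and none higher, with a median log2 difference of -4.41 (camera adjusted p = 5.76e-14; adjusted p = 0.174 with an estimated correlation). Fbln5, which encodes an elastic fibre protein, fell by 6.48. Of 26 fibroblast and mesenchymal identity genes, 20 were called lower and none higher, with a median of -2.18 (camera adjusted p = 1.1e-11; adjusted p = 0.0417 with an estimated correlation). The caveolae gene Cav1 fell by 5.86, the platelet-derived growth factor receptor gene Pdgfrb by 5.18 and the intermediate filament gene Vim by 4.81. Of 17 smooth muscle and actin cytoskeleton genes, 14 were called lower and none higher (median -4.07, camera adjusted p = 8.43e-09; adjusted p = 0.102 with an estimated correlation). Tagln fell by 6.60, Tpm2 by 5.69 and Cnn1 by 5.25, all 3 encoding actin-associated proteins of contractile cells. Of 17 genes in the list named TGF-beta and BMP target genes, 10 were called lower and none higher. The median was -1.57 (camera adjusted p = 9.07e-07, and 0.102 with an estimated correlation). The ligand genes Tgfb3 and Tgfb2 (-6.29) and the latent TGF-beta binding protein gene Ltbp1 (-4.55) led. The list thus holds components of the pathway as well as targets, and does not measure the output of the pathway alone. The 57 genes of the matrix, mesenchymal and smooth muscle lists that were called lower differed among the rat ES arrays: they lay higher on rat ES array 3 than on array 1 by a median of 0.25 on the log2 scale, in 43 of the 57 genes.

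**Figure D2:**
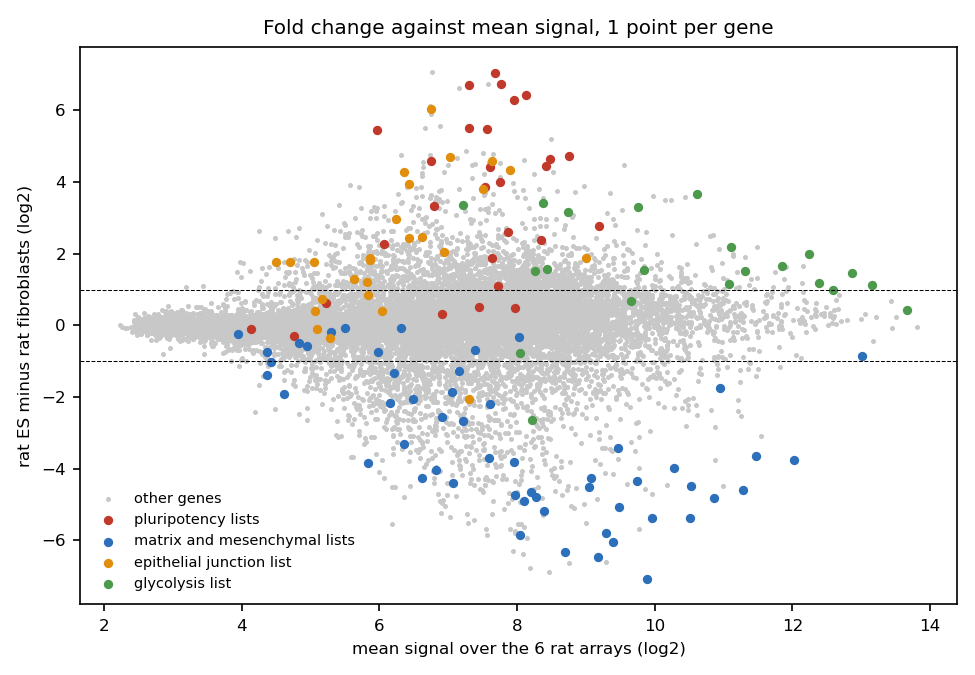
Log2 difference between rat ES cells and rat fibroblasts (vertical axis) against mean signal over the 6 rat arrays (log2, horizontal axis), with 1 point per gene and dashed lines at 2-fold. Genes of the pluripotency lists (red) lie mostly above the upper line and genes of the matrix and mesenchymal lists (blue) mostly below the lower line, down to -7.07 for Thbs1. Epithelial junction genes (orange) and glycolysis genes (green) lie mostly above the upper line, and other genes are grey.

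Of 26 epithelial junction genes, 19 were called higher and 1 lower, with a median of 1.84 (camera adjusted p = 9.06e-08; adjusted p = 0.165 with an estimated correlation). Epcam, an epithelial adhesion molecule, was 65.6-fold higher, E-cadherin (Cdh1) 25.9-fold and the keratin gene Krt18 23.9-fold, whereas the desmosomal gene Pkp2 fell by 2.05. The fibroblast signals of Epcam (3.73), Cdh1 (4.68) and Krt18 (5.34) lay below the array medians, so these folds are uncertain. Of 31 cell cycle and DNA replication genes, 19 were called higher and none lower, with a median of 1.35 (camera adjusted p = 7.17e-11; adjusted p = 0.0417 with an estimated correlation), led by the transcription factor gene Mybl2 (3.61), the replicative helicase gene Mcm5 (2.14) and the ribonucleotide reductase gene Rrm2 (2.14). Of 19 cell cycle inhibitors and p53 targets, 9 were called lower and 3 higher, and the list missed the threshold (camera adjusted p = 0.0501; adjusted p = 0.335 with an estimated correlation; fry adjusted p = 6.54e-05). With camera at its preset correlation, adjusted p ranged from 0.0416 to 0.0635 over the other settings. Cdkn2a fell by 3.41, Cdkn2b by 3.12 and the death receptor gene Fas by 2.41, while Perp (2.29) and Tp53inp1 (1.28) were higher. Of 21 glycolysis genes, 16 were called higher and 1 lower, with a median of 1.52 (camera adjusted p = 2.28e-07; adjusted p = 0.103 with an estimated correlation). The glucose transporter gene Slc2a1 differed by 3.67, the lactate transporter gene Slc16a3 by 3.43 and Aldoc by 3.36, against -2.65 for the neuronal enolase gene Eno2. Of 21 DNA methylation and chromatin regulators, 9 were called higher and none lower (median 0.75, camera adjusted p = 0.00103; adjusted p = 0.102 with an estimated correlation), led by Dnmt3l, Uhrf1 (2.61), which recruits the maintenance methyltransferase, and Dnmt3b. Of 14 germ cell markers, 9 were called higher and 1 lower (median 1.26, camera adjusted p = 2.5e-04; adjusted p = 0.102 with an estimated correlation). Dppa3, Sohlh2 (5.90) and Tex19.1 (4.76) were the largest increases, and Prdm1, a regulator of germ cell specification, fell by 1.51. The signals of Prdm1 lay below the array medians in both groups (4.01 in rat ES cells, 5.52 in fibroblasts). This list lost its call among genes above the median of mean level (camera adjusted p = 0.0860). Dppa3 is also in the naive list, and Dnmt3l also in the general pluripotency list.

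The next 3 lists, of signalling genes, held members called in both directions; camera called none of them, and fry called all 3. Rat ES cells were in 3I medium and fibroblasts in serum medium. Differences in these lists, as in every other list of the rat comparison, therefore cannot be assigned to cell type or medium. Of 25 FGF/MEK/ERK feedback and target genes, 8 were called lower and 5 higher (camera adjusted p = 0.0917, fry adjusted p = 6.87e-04). The immediate early gene Egr1 fell by 4.44 and Myc by 3.31, while Dusp4, which encodes a phosphatase of ERK, was higher by 3.39 and the feedback inhibitor gene Spry2 by 1.87. Of 16 Wnt/beta-catenin target genes, 6 were called higher and 2 lower (camera adjusted p = 0.533, fry adjusted p = 0.00527), with Lef1 (3.96) and Cdx2 (3.80) higher and Ccn4 (-4.17) and Nkd2 (-2.82) lower. Of 16 LIF/STAT3 pathway genes, 5 were called higher and 4 lower (camera adjusted p = 0.548, fry adjusted p = 1.01e-05). The LIF receptor gene Lifr was 37.0-fold higher, Tfcp2l1 44.6-fold and Socs2, a suppressor of cytokine signalling, higher by 3.05, while Lif itself fell by 2.00 and Junb by 1.85. The fibroblast signals of Tfcp2l1 (4.83), Socs2 (4.54) and Cdx2 (5.26) lay below the array medians, as did the rat ES signals of Egr1 (5.16) and Myc (4.12). The sizes of these differences are uncertain.

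Of 18 primitive endoderm markers, 6 were called lower and 2 higher (camera adjusted p = 0.0478; adjusted p = 0.178 with an estimated correlation). The decreases were led by Dab2 (-4.28) and the basement membrane collagen gene Col4a1 (-3.96), and the increases were in the laminin gene Lama1 (4.52) and Hnf4a (1.14). This list lost its call after quantile normalization (camera adjusted p = 0.0708), with the filter at the 25th percentile of level (0.0512) and without fibroblast array 3 (0.0617). Of 12 neural markers, 4 were called lower and none higher (camera adjusted p = 0.0338; adjusted p = 0.165 with an estimated correlation), led by Map2 (-3.39), Ncam1 (-3.25) and Nes (-1.87). The neural list lost its call without fibroblast array 3 (camera adjusted p = 0.0535) and among genes above the median of mean level (0.114). Of 14 cartilage and bone markers, 5 were called lower and 1 higher (camera adjusted p = 0.00844; adjusted p = 0.112 with an estimated correlation), with Col11a1 (-4.99), Spp1 (-4.57) and Acan (-3.51) lower and the alkaline phosphatase gene Alpl (2.34), also used as a stain for ES colonies, higher. Of 11 trophoblast markers, Cdx2 and Tfap2c (3.34) were called higher and Gata3 (-1.71) lower, and the list was not called (camera adjusted p = 0.866). Its median was below 0 at -0.06 while its mean and test pointed up. Of 10 mesoderm and primitive streak markers, 1 was called, Tbxt, higher by 1.78 (camera adjusted p = 0.551). The median of this list was -0.12 and its test pointed down, while its mean was above 0 at 0.05.

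Of 13 endothelial markers, Tie1 (3.00) and Cldn5 (2.05) were called higher and 3 were called lower, Flt1 (-1.60) the most among them (camera adjusted p = 0.641). Median (0.01) and mean (0.04) of this list were above 0 while its test pointed down. Of 16 blood and macrophage markers, Laptm5 (3.87) and the erythroid transcription factor gene Gata1 (3.07) were called higher and Cd14 (-3.51) lower (camera adjusted p = 0.678). Of 13 skeletal and cardiac muscle markers, Tnnc1 (-4.89) and Acta1 (-1.28) were called lower and none higher (camera adjusted p = 0.0543). Camera called the muscle list without fibroblast array 1 (adjusted p = 0.0486) or 2 (0.0436) and with the replicate number as a block (0.0471). None of 10 adipocyte markers and none of 7 keratinocyte markers was called by limma, where 3 and 1 had an unadjusted p under 0.05. These 3 and 1 also had an adjusted p under 0.05 but differed by less than 2-fold. Camera gave these 2 lists adjusted p = 0.402 and 0.641, and fry 0.13 and 0.135. Of the X and Y linked sex genes, 1 was measured and it was not called, with no gene at an unadjusted p under 0.05 (camera adjusted p = 0.825, fry adjusted p = 0.5).

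Of 22 imprinted genes, 7 were called lower and 2 higher (camera adjusted p = 0.0917, or 0.0386 among genes above the median of mean level), with Grb10 (-4.63), Slc38a4 (-3.03) and Gnas (-2.07) lower and Nnat (1.54) and Dio3 (1.23) higher. Gnas was at -0.85, under 2-fold, when all its probe sets were averaged, and Dio3 was at 0.98 without rat ES array 3. Of 22 Hox cluster genes, 3 were called lower, Hoxd13 (-2.56), Hoxd10 (-1.68) and Hoxa2 (-1.40), and 3 were called higher (camera adjusted p = 0.0917). Of 24 MHC class I and interferon response genes, Ifitm1 (6.61) and Gbp2 (1.43) were called higher and 3 were called lower, among them Ifitm3 (-1.90) and Ifit2 (-1.54), with a camera adjusted p of 0.331. The median of this list was -0.08 and its test pointed down, while its mean was 0.03. Of 15 heat shock and stress genes, 4 were called higher, among them Nqo1 (2.31) and Hsp90aa1 (1.66), and 2 lower, Hspb1 (-3.12) and Hspa5 (-1.22), with a camera adjusted p of 0.0917. Of 35 cytosolic ribosomal protein genes, limma called none, where 15 had an unadjusted p under 0.05. An adjusted p under 0.05 was reached by 14 of them, all at less than 2-fold. Camera gave this list adjusted p = 0.0917 and fry 2.91e-05.

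In every list, the number of members called was the same when p-values were adjusted over the list alone. Of the 32 lists, camera with its preset correlation called 14, camera with an estimated correlation called 4 and fry, which tests only whether a list's own genes moved on balance in a single direction, called 26.

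**Figure D3:**
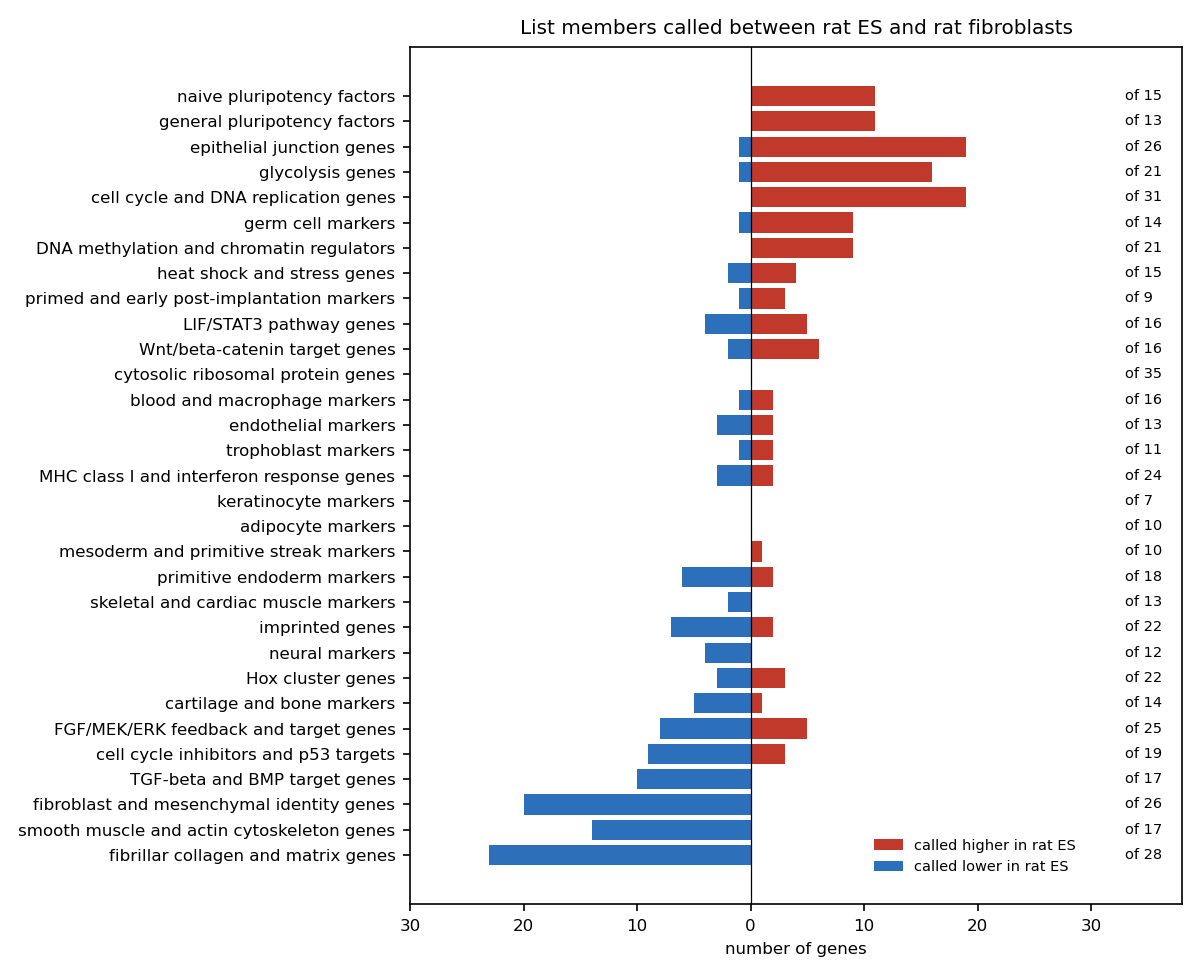
Number of members of each fixed list that were called higher (red, to the right) or lower (blue, to the left) in rat ES cells than in rat fibroblasts, with the number measured at the right edge and lists ordered by median log2 difference. The matrix list has 23 of 28 members lower and the naive list 11 of 15 higher; the sex gene list, with 1 measured member, is not drawn.

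The second comparison asked which rat cell type the mouse ES cells resembled. Across 12114 genes measured under the same symbol on both platforms, mouse ES arrays ranked genes more like rat ES arrays than like rat fibroblast arrays. Spearman's rho averaged 0.834 (range 0.826 to 0.839 over 9 pairs of arrays) with rat ES cells and 0.749 (range 0.744 to 0.752) with rat fibroblasts. The difference of 0.0844 had p = 0.1 in an exact two-sided permutation of the 6 rat arrays, the smallest p this design allows. These correlations are across genes, which are not independent replicates. Rat ES cells correlated with rat fibroblasts at a mean rho of 0.837. Among genes above the 25th percentile of level on both platforms the difference was 0.158. Mouse and rat tables were normalized separately, and species, strain, medium and array platform all differ between the ES groups, so levels were set side by side only as ranks within an array.

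Genes that separated the 2 rat groups were then located in mouse ES cells. The 1419 shared genes called higher in rat ES cells had a median percentile of 70.0 in mouse ES cells, against 78.2 in rat ES cells and 49.0 in rat fibroblasts. The 1385 shared genes called higher in rat fibroblasts had a median percentile of 48.6 in mouse ES cells, against 42.2 in rat ES cells and 80.4 in rat fibroblasts. The difference of 21.4 percentile points in mouse ES cells lay outside the range of -1.57 to 5.62 given by 10000 random pairs of lists matched on rat expression. Of the 12114 shared genes, 6367 had the same deposited value on all 3 mouse arrays, so a spread over mouse arrays understates the error and is not given here. Among the 2165 genes with a different value on each mouse array, an alternative chosen after seeing the data, the difference was 15.1.

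Both pluripotency lists ranked high in the ES cells of both species. The 13 shared naive pluripotency factors had a median percentile of 85.2 in mouse ES cells, 91.5 ± 0.5 (SD, n = 3) in rat ES cells and 24.0 ± 0.606 in rat fibroblasts. The 13 general factors stood at 92.9 in mouse ES cells, 88.6 ± 0.231 in rat ES cells and 35.0 ± 2.17 in rat fibroblasts. Fibrillar collagen and matrix genes stood at 45.7 in mouse ES cells, 54.4 ± 2.94 in rat ES cells and 99.4 ± 0.0186 in rat fibroblasts. Epithelial junction genes stood at 79.9 in mouse ES cells, 51.6 ± 1.02 in rat ES cells and 22.4 ± 0.653 in rat fibroblasts. FGF/MEK/ERK feedback and target genes stood at 77.7 in mouse ES cells, 60.4 ± 0.892 in rat ES cells and 59.3 ± 0.75 in rat fibroblasts. Differences of similar size and direction between mouse and rat ES cells were present in lists of other kinds. Imprinted genes stood at 73.0 in mouse ES cells and 48.3 in rat ES cells, and trophoblast markers at 56.2 and 32.5. Endothelial markers stood at 45.6 and 27.7, and smooth muscle and actin cytoskeleton genes at 59.5 and 43.2. Wnt/beta-catenin target genes stood at 33.6 in mouse ES cells and 47.1 ± 0.935 in rat ES cells. With percentiles taken among all named genes of an array, the difference between mouse and rat ES cells went from -13.5 to -8.08 for the Wnt list and from -6.36 to -3.06 for the naive list. LIF/STAT3 pathway genes stood at 68.6 and 70.8 ± 0.358, and the sign of that difference turned when percentiles were taken among all named genes of an array. No test was made across the tables.

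**Figure D4:**
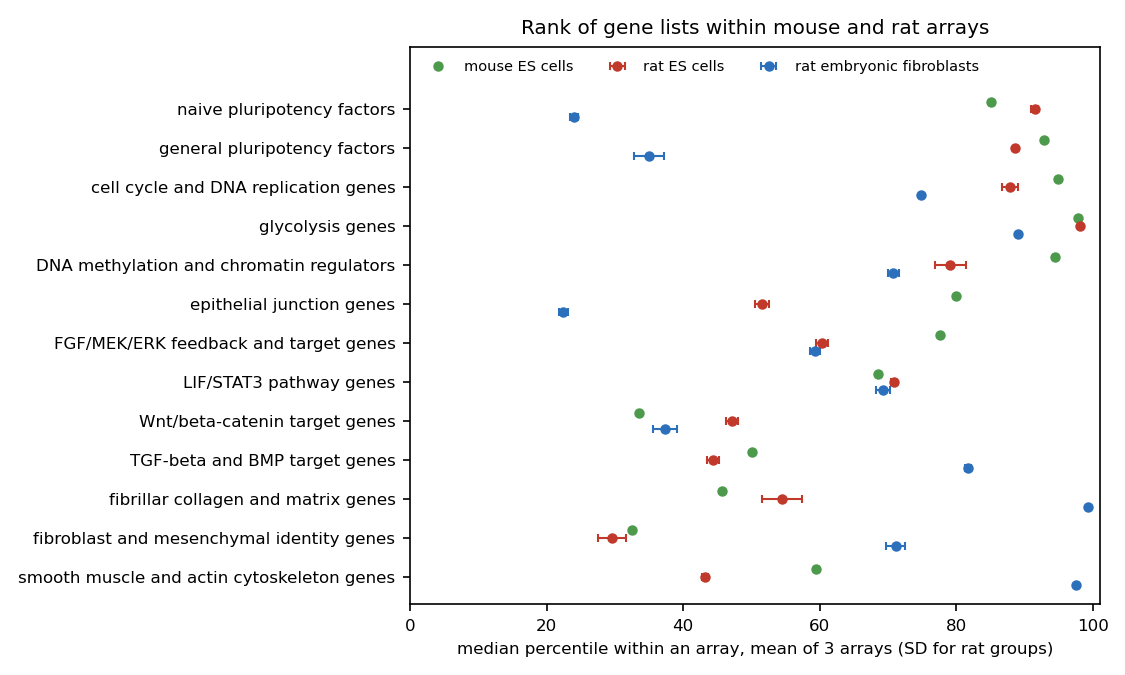
Median percentile of the genes of each list within an array (horizontal axis), as the mean of 3 arrays for mouse ES cells (green), rat ES cells (red) and rat fibroblasts (blue), with SD bars for the rat groups. The naive list lies at 85.2, 91.5 and 24.0, and the matrix list at 45.7, 54.4 and 99.4.

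Single list members differed in rank between the ES cells of the 2 species with all 3 arrays of a group above all 3 of the other. The 6 with the largest differences toward mouse were Nr0b1, Myc, Phlda2, Cubn, Cd68 and Plac1. Nr0b1, an orphan nuclear receptor gene used as a marker of mouse ES cells, stood at percentile 99.1 in mouse ES cells, 16.8 ± 0.462 (SD, n = 3) in rat ES cells and 20.7 ± 3.44 in rat fibroblasts. Myc stood at 91.6 in mouse ES cells and 10.9 ± 7.43 in rat ES cells, and the placental growth regulator Phlda2 at 93.2 and 15.8 ± 4.65. The 6 with the largest differences toward rat were Postn, Jak2, Cdx2, Hoxa5, Tie1 and Sohlh2. Cdx2, a caudal-type homeobox gene of trophectoderm and hindgut, stood at 28.2 in mouse ES cells, 87.4 ± 0.799 in rat ES cells and 26.9 ± 2.68 in rat fibroblasts. The matrix gene Postn stood at 4.82 in mouse ES cells, 68.7 ± 7.95 in rat ES cells and 99.9 ± 0.00477 in rat fibroblasts. Its signal differed among rat ES arrays 1, 2 and 3 (7.31, 7.90 and 8.26), as did that of other fibroblast list genes, and feeder removal is stated for the mouse cultures only. Each such difference rests on different probes on different platforms. For 7 of these 12 genes the 3 deposited mouse values were identical, so that 3 mouse arrays above or below 3 rat arrays is weak evidence of separation.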

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

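Besides the genes that carry a symbol, 13582 rat probe sets with no symbol listed were measured. They enter the array medians and the correlations between rat arrays above, but none of the gene and list tests. Tested with limma over all rat probe sets, 1313 of the unnamed ones were called changed between rat ES cells and fibroblasts, 847 higher in rat ES cells and 466 lower. This is 9.67% of them, against 20.7% of the named genes tested. The 2 largest increases were in probe sets 10746588 (log2 difference 7.43, SE 0.13, limma adjusted p = 4.84e-08) and 10718749 (7.03, SE 0.07). The 2 largest decreases were in 10769693 (-6.01, SE 0.08) and 10869616 (-5.74, SE 0.15). What these probe sets measure was not determined here.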

How the results depend on the processing

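The count of 2996 called genes stayed between 2199 and 3035 over the normalizations, filters, mean of probe sets, variance settings, the test against 2-fold and the arrays left out. Without each array it was 2994 to 3035. Only 2 other thresholds moved it further. At any fold, 8172 genes passed (4478 higher, 3694 lower), and at 4-fold with adjusted p under 0.01, 995 (378 higher, 617 lower). With every probe set apart, unnamed ones included, 4442 of 29215 probe sets were called, 2484 of them higher in rat ES cells. This counts probe sets and not genes, so it cannot be set against 2996. A model with the replicate number as a block called 2996 genes, all 2996 shared with the model without it, and 15 lists. It added the skeletal and cardiac muscle list (adjusted p = 0.0471) and changed no other call. Camera with an estimated correlation called 4 of 32 lists and fry 26. The p53 and inhibitor list, just outside the threshold, was called after quantile normalization (0.0463) and without rat ES array 2, rat ES array 3 or fibroblast array 1, where camera adjusted p was 0.0416 to 0.0486. The imprinted list was called among genes above the median of mean level (0.0386). The muscle list was also called without fibroblast array 1 (0.0486) or 2 (0.0436). Of 1884 recomputed values for 119 named genes, 1850 kept their call or lack of it, 30 lost a call and 4 gained it. None with a call in the main or the other setting turned sign. A turned sign in a gene called in neither was not counted.

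The difference in rho was 0.0928 with Pearson's r, 0.158 above the 25th percentile in both tables, 0.0828 over genes that differ on all 3 mouse arrays and 0.0838 to 0.0852 without each array. The difference in percentile was 23.2 with 4-fold lists, 15.1 over genes that differ on all 3 mouse arrays and 20.9 to 22.0 without each array. The percentile of naive factors in mouse minus rat ES cells went from -6.36 to -3.06 among all named genes and -4.55 with the mean of probe sets, and that of general factors from 4.21 to 5.28 among all named genes. Among all named genes the LIF/STAT3 difference turned from -2.26 to 2.18, the Wnt/beta-catenin difference went from -13.5 to -8.08 and the FGF/MEK/ERK difference from 17.3 to 18.7. Why the other values moved was not tested. Signal over background could not be judged, since no background values were used.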

Other observations

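The stricter definition of gene families was chosen after the first result on neighbours had been seen, the bounds of the tests on copies among the mouse arrays and on tandem gene families were reworded after their values had been seen, the 25 probes used for median polish were picked after its simulation, and the genes named in the next paragraphs as examples were chosen after their values were seen.

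Genes called in the rat comparison lay beside each other along the chromosomes more often than in random orders. Among 14480 genes with a place in the rat gene table, genes higher in rat ES cells formed 242 neighbouring pairs, against a mean of 163 and a highest count of 210 over 10000 random orders, and genes lower in rat ES cells formed 209, against a highest random count of 192. A run of 4 genes higher in rat ES cells held Gdf3, Dppa3, Nanog and Slc2a3, and a run of 6 lower genes held Mdfic, Tfec, Tes, Cav2, Cav1 and Met, while 2 runs of higher genes held mainly histone genes, a clustered family whose members differ in name stem. Without pairs that share a name stem, 225 pairs of higher genes remained, above the highest of 184 in random orders, and without pairs of histone genes or of symbols with the same first 2 letters, 219 remained (highest 184), which argues against tandem gene families as the whole source. Of 700 neighbouring pairs of different name stem with both genes called, 415 had 1 direction, above the highest of 397 when directions were shuffled. Neighbours thus shared a direction more often than the places of the called genes alone gave. The shuffle did not hold expression level or kind of gene fixed, so it cannot decide on clustering of genes expressed in 1 cell type.

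In 57 genes of the fibroblast lists, the excess of rat ES array 3 over array 1 had a median of 0.862% of the fibroblast level. Its quartiles were 0.107% and 1.93%. The excess was 4.38% for Col1a1, 3.36% for Sparc, 1.67% for Col3a1, 1.59% for Postn, 1.52% for Bgn, 1.32% for Vim and 0.862% for Fbn1. These 7 abundant genes all lay at or above the median, so they do not stand for the whole set. A background or scaling difference is argued against by genes of matched rat ES level, whose median shift was 0.0187 against 0.25 for the list genes. A small share of fibroblast-like cells on array 3 may account for it: 69.7% of 89 genes at least 16-fold lower in rat ES cells and in none of the lists lay higher on array 3, against 54.2% of all unchanged genes and between the bounds of 60 and 80 set for a decision, which leaves it open. Differentiation toward other lineages also stays open, since 40 lineage genes not higher in fibroblasts had a median shift of -0.0188 with quartiles on both sides of 0. These explanations cannot be told apart with 3 arrays, and the labels do not say whether feeder cells were removed from the rat ES cultures.

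The 3 mouse ES arrays hold the same value for 43.4% of probe sets, and none of the rat probe sets has 1 value on all 3 arrays of a group. Copies of a single array are argued against by the probe sets that were not identical, which differed between mouse arrays by a median of at least 0.125 on the log2 scale, against 0.114 to 0.131 between rat replicates. The bound first written, at least the highest rat pair, was not met by 0.125, and the bound used, the median of the rat pairs, was set after that. A hypothesis is that probes were summarized by median polish over 3 arrays: in 2000 simulated probe sets it made 79.8% equal on all 3 arrays with 25 probes, but 16.6% with 10 probes, under the 20% asked for, and over 6 arrays 0% equal on a pair. All simulated arrays had the same true value for a probe set, with no cell types that differ, so these shares cannot be set directly against the 43.4%. The method the authors used is not given in the sources used here.

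In the rat comparison, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, called 2996 genes, and the highest count of the other splits was 0. With 10 splits the share can never be under 0.05. Every other split also put arrays of both cell types in each group, so the difference between these cells and their media widened the spread within groups. Their count of 0 was therefore built in and is no evidence on chance.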
